A study of Mus musculus with 4 samples.

How the data were processed

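Bulk RNA-seq counts of 4 mice were analysed, each mouse giving 1 library of 50 sorted cells. Per the labels, tdTomato was delivered to the cells by an adeno-associated virus injected into a brain ventricle, tissue around the central canal was digested and dissociated, and live tdTomato-positive cells were sorted with an uninjected preparation as the negative control, which was not analysed here. Complementary DNA was made with the SMART-Seq v4 kit and 11 PCR cycles, and libraries with the Nextera XT kit, per the labels. These libraries cover whole transcripts, do not keep the strand and carry no molecular identifiers, so counts grow with transcript length, reads of a gene and an overlapping partner cannot be told apart, and intervals and floors below cover counting error only.

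The authors deposited whole-number counts per gene for 42458 rows, with 2 columns per mouse. Per the submitters' processing notes, FastQC, Trim Galore, STAR, RSEM and DESeq2 were used with build mm10. Their roles, versions and settings, the gene annotation and any rounding of RSEM estimates are not given in the sources used here. The columns carry sample numbers from 1 to 4, taken as the mouse numbers of the labels. The 2 columns of a mouse had a Spearman correlation of 0.9979 to 0.9986 across genes. Their mean chi-square was 1.94 to 2.21 per gene, where counting error alone would give about 1, so they differed by more than counting error. They were treated as repeat runs of a library: their counts were summed, so that a mouse counts as 1 replicate. The authors also deposited a table of log2 values. From the values, it equals log2 of the summed counts of a mouse divided by a size factor (1.18, 1.05, 0.936 and 0.983 in mice 1, 2, 3 and 4), plus 1. It was used only as an alternative. In it 26 gene names had been turned into dates. No row lacked a gene name, and no column was left without a sample.

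The table holds 2346 rows whose name is that of another row plus a number, of which 971 have counts and 345 repeat the counts of the row without the number. These rows held at most 1.67% of a library and were kept. Hspa1a, Hspa1b and Trem2 have such copies, and the alpha globin genes Hba-a1 and Hba-a2 are near-identical, so their values are uncertain. The mitochondrially encoded rows were only the 2 ribosomal RNA genes, at 0.302%, 0.336%, 0.303% and 0.344% of counts. Gene positions and exonic lengths come from GENCODE M21 on GRCm38, the assembly also called mm10. A gene model was found for 27954 rows, which held 97.3% of the counts, and for all 452 genes of the fixed lists.

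Before the data were examined, 27 gene lists with 452 genes and no shared member, the tests, the alternatives and the rule for named genes were fixed. The lists cover cell types, opioid genes, Gi/o signalling, peptides, channels, receptors, growth factors, the cell cycle and the response to dissociation. The genes named are all 8 opioid genes, all 9 CSF-cN markers, the 4 members with the highest mean CPM of each other list (all members of lists of 5 or fewer), the 10 genes with the highest mean CPM, and the 10 with the largest SD of log2(CPM + 1) among genes with a mean of at least 100 CPM. Some genes that the rule takes are not reported here. Other names were added after their values were seen: Foxj1, Pkd2, PC.G5.tdT and CRE.ERT2, and the genes and lists said to be so where they appear. Foxj1 and Pkd2 belong to gene pairs fixed beforehand.

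CPM were computed from the deposited counts with edgeR's TMM normalization (factors 0.935, 0.982, 1.04 and 1.05). The level test asked for each gene with at least 10 counts in total whether its level differed from 10 CPM. A quasi-likelihood model with an intercept only was fitted with edgeR 4.0.16 in R 4.3.3, with an offset that makes an intercept of 0 mean 10 CPM. The tool's own test function does not accept a single-column design, so the same F test was computed from the fitted deviances, including its bound by the Poisson test. The printed SE is the size of the log2 level divided by the square root of F. P-values were adjusted by the Benjamini-Hochberg method over the 18522 tested genes, or over a list alone where said, with a threshold of 0.05. The model takes the mean over mice on the count scale, so a gene can be called with low values in some libraries.

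Marker lists were compared within a mouse by the difference of their median log2(CPM + 1), and 9 gene pairs by the log2 ratio of CPM + 1. Both used an exact two-sided sign-flip permutation test over the 4 mice (16 sign patterns, smallest p 0.125), with adjustment over 15 lists or 9 pairs. In 3 of the pairs (Oprk1 with Oprd1, Slc32a1 with Slc17a6 and with Chat) the other gene had no count, which fixes the sign, so their tests are not read, though they stay in the adjustment. Intervals are 95% Clopper-Pearson intervals on the counts. The floor is 3 counts. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these steps.

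The tests were tested on simulated data. For the level test, with 17144 genes in the simulated run, edgeR called 47 of 50 genes set at 4 times 10 CPM, 49 of 50 at 16 times, 0 of 50 at 0.25 times and 0 of 50 at 0.0625 times, and 8 of 200 genes set at 10 CPM. It thus called none of the genes simulated at these levels below 10 CPM. DESeq2 called 41, 44, 2 and 8 of 50 and 4 of 200. limma-voom called 35, 47, 14 and 48 of 50 and 23 of 200, with a median log2 of -0.53 for genes set at 10 CPM, since it averages logs and so falls below the mean when mice vary. In this level simulation the spread between mice was only that of edgeR's fitted trend. Genes that are nearly without counts in some libraries and high in others vary more than this. The rates need not hold for them, and a missing call does not show a low level in every mouse. For the list comparison with 18 genes, simulated differences of 2 and 6 had median estimates of 1.92 and 5.99 and reached the smallest p in 50 of 50 data sets each, and with no difference the median estimate was 0.0945 and 4 of 50 data sets reached it. The simulated genes varied independently of each other, with a negative binomial size of 2 and a shared mean per list. Members of real lists can rise and fall together by mouse, so these rates need not hold for the real lists.

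The alternatives were DESeq2 size factors or total counts in place of TMM, library sizes without mitochondrial rows, leaving out each mouse, DESeq2 1.42.0 and limma-voom (limma 3.58.1), reference levels of 1 and 100 CPM, no filter or at least 10 counts in 2 samples, a pseudocount of 0.1, the mean of list members, scaling by exonic length, and the deposited log2 table. Leaving out mice 1 and 2 together was added after the data were seen.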

Results

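RNA of 50 sorted cells was sequenced from the spinal cord of each of 4 C57BL6 mice. Per the labels, the mice had received an adeno-associated virus coding for the red fluorescent protein tdTomato into a brain ventricle. The labels also state that tissue around the central canal was dissociated and that live cells positive for tdTomato were collected by fluorescence-activated sorting to enrich cerebrospinal fluid-contacting neurons (CSF-cNs), neurons at the central canal with a process in the fluid; the libraries of mice 1 and 2 held only 5 and 58 counts of the transgene. The 4 libraries form a single group with 1 library per mouse, so the data allow levels within the group and the spread between mice, and no comparison between groups. The total counts were 115479640, 95186395, 83007030 and 85626022 in mice 1, 2, 3 and 4, and lists of 4 values keep this order throughout. A count was recorded for 15773, 15869, 17291 and 16893 genes. At these depths a count of 0 allowed levels of up to 0.0278, 0.0321, 0.0348 and 0.0334 CPM (the count scaled to a fixed library size, with TMM normalization), which is 3 counts and covers counting error only.

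The series title concerns opioid signalling of spinal cells, and the labels state that CSF-cNs were enriched, so the transcripts that mark CSF-cNs were examined before all others. Pkd2l1, the polycystin channel gene that marks these neurons, reached 17.9, 0.193, 664 and 690 CPM, a mean of 343 ± 386 CPM (SD, n = 4). Most other members of the list of 9 CSF-cN markers were also present in the libraries of mice 3 and 4 and nearly without counts in those of mice 1 and 2. The channel gene Pkd1l2 stood at 0.0463, 0, 108 and 47.9 CPM and the myosin gene Myo3b at 0.0370, 0, 80.3 and 62.7 CPM. The transcription factor genes Gata2 (0, 0.0107, 24.2 and 5.65 CPM), Gata3 (0, 0, 16.2 and 7.38 CPM) and Tal2 (0.00926, 0, 20.1 and 5.69 CPM) were lower. Tal1, another such factor, was at 0.898, 10.3, 10.8 and 14.8 CPM, and the actin-bundling gene Espn at 1.44, 2.39, 17.3 and 11.7 CPM. P2rx2, which codes for an ATP-gated channel, had no count in any of the 4 libraries. The summed level of the list was 20.3, 12.9, 941 and 846 CPM.

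The tdTomato transgene differed between the libraries as well. It had 5, 58, 13533 and 153379 counts, or 0.0463, 0.621, 157 and 1709 CPM, values that are uncertain because it was not determined whether a further construct row with tdT in its name takes reads of the same sequence. Pkd2l1 lies on chromosome 19 from 44147637 to 44192442 on the minus strand of GRCm38 (gene ENSMUSG00000037578.4). It was the only one of the 8 tested CSF-cN markers called above 10 CPM by edgeR's quasi-likelihood test (log2 level relative to 10 CPM 5.10, SE 0.57, Benjamini-Hochberg adjusted p = 3.5e-04), and the count adjusted over the list alone was also 1. limma-voom, which averages on the log scale, did not call Pkd2l1 (adjusted p = 0.36) or any other member. Without mice 1 and 2, an alternative chosen after the data were seen because of their few transgene counts, 3 members were called, namely Pkd2l1, Pkd1l2 and Myo3b. Pkd1l2 and Myo3b were nearly without counts in the libraries left out, so their calls follow from the choice of samples.

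**Figure D1:**
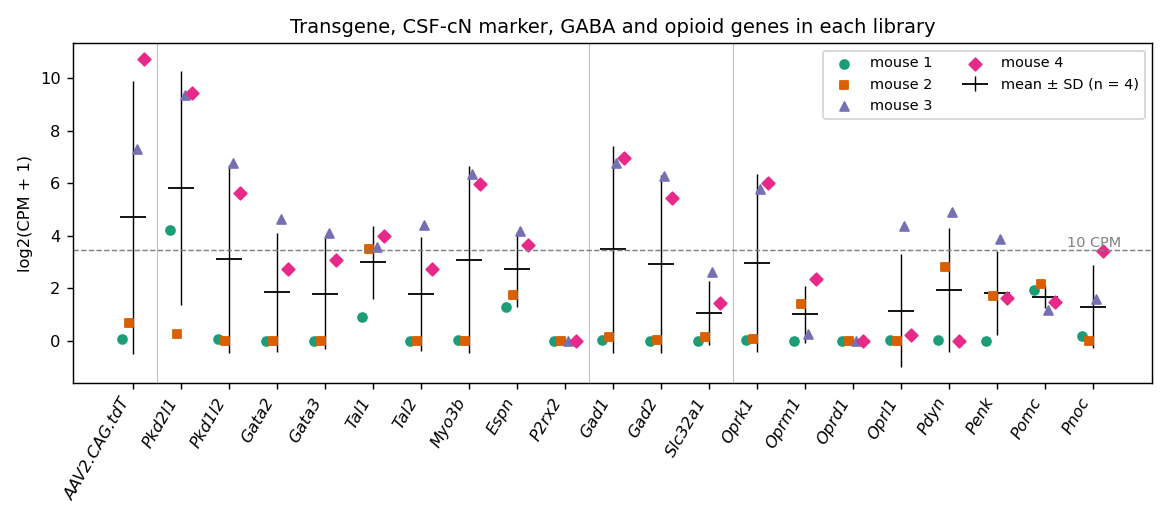
Level of the tdTomato transgene, the CSF-cN markers, 3 genes of GABA synthesis and transport and the 8 opioid genes in each library, as log2(CPM + 1) on the vertical axis. Points are the 4 mice, the horizontal bar and whisker are their mean ± SD, and the dashed line is 10 CPM; the points of mice 1 and 2 lie near 0 for Pkd1l2, Gad1 and Oprk1, while those of mice 3 and 4 lie above the line.

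Microglial transcripts were the most abundant cell type signal in each of the 4 libraries. All 10 microglia markers were called above 10 CPM (10 adjusted over the list alone) and stood at 10 CPM or more in every library. The list summed to 53304, 59245, 35143 and 51133 CPM, which was 4.98%, 5.82%, 3.65% and 5.36% of all counts. The purinergic receptor gene P2ry12 had a mean of 7288 ± 1381 CPM (SD, n = 4), the complement gene C1qb 6624 ± 1867 CPM and the growth factor receptor gene Csf1r 5081 ± 1275 CPM. The 10 genes with the highest mean included Cst3, Malat1, Ctss, Ctsd, Serinc3, Itm2b, P2ry12, C1qb and Gpr34, from 29615 CPM for Cst3 to 6352 CPM for Gpr34. Across all 18522 tested genes, edgeR called 6795 above and 123 below 10 CPM. Of the 6795 genes, 6456 were at 10 CPM or more in all 4 libraries, 284 in 3 and 55 in 2. The 123 calls below 10 CPM fell to 0 without any single mouse, and the test found none of the simulated genes placed below 10 CPM, so the number of genes below that level was not measured reliably.

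Oligodendrocyte transcripts were high in the libraries of mice 1 and 3 and low in those of mice 2 and 4. The list summed to 15065, 238, 19260 and 459 CPM, and 8 of its 10 members were called above 10 CPM by edgeR (8 adjusted over the list alone) and 5 by limma-voom. The myelin basic protein gene Mbp was at 1312, 31.3, 1690 and 217 CPM, and the myelin enzyme gene Cnp at 898, 103, 1440 and 70.5 CPM. Ermn was at 710, 2.03, 964 and 0.981 CPM and was not called by limma-voom (adjusted p = 0.31). Of the astrocyte list, 3 of 10 members were called above 10 CPM (3 adjusted over the list alone). Of these, the glycolytic gene Aldoc (835, 11.6, 846 and 118 CPM) and S100b (298, 4.2, 440 and 10.5 CPM) had their higher values in the same libraries as Mbp, and the glutamate transporter gene Slc1a3 had a mean of 111 ± 42.8 CPM (SD, n = 4). S100b was not called by limma-voom (adjusted p = 0.071).

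Most markers of the remaining non-neuronal cell types were not called above 10 CPM. None of the 12 ependymal markers was called above 10 CPM, and the list summed to 0.0370, 0.514, 16.9 and 82.2 CPM. In mouse 4 the ependymal genes Ccdc153, Mia, Fam183b and Rarres2 stood at 15.8, 12.5, 12.2 and 10.2 CPM. No tested member was called for oligodendrocyte precursors (57.4, 1.41, 79.6 and 16.9 CPM summed), endothelium (21.3, 12.5, 16.4 and 29.0 CPM), mural cells (0.157, 0.0321, 0.0116 and 4.99 CPM) or red blood cells (3.44, 2.43, 1.68 and 3.10 CPM). The fibroblast list summed to 11.5, 0.203, 1023 and 116 CPM. Of its 4 tested members the proteoglycan gene Dcn was called (1.41, 0.0963, 989 and 108 CPM; 1 adjusted over the list alone), and this call was lost without mouse 3 (edgeR adjusted p = 0.32) and under limma-voom, while DESeq2 gave no adjusted p for Dcn. Dcn alone made up most of the fibroblast sum in mice 3 and 4, so this sum reflects mainly 1 gene. Lum had counts in mouse 4 alone (0.769 CPM), and Igf2 was at 3.08, 0.0963, 29.5 and 6.61 CPM. For the 5 of these lists with a count of 0, edgeR called 0 members above 10 CPM at an unadjusted p under 0.05, and limma-voom also called 0 above; it called 10 of 12 ependymal, 2 of 6 oligodendrocyte precursor, 2 of 4 endothelial, 4 of 4 mural and 3 of 3 red blood cell genes below 10 CPM. DESeq2 called 0 above as well, and 1 oligodendrocyte precursor and 2 mural genes below, but gave no adjusted p for 8 of 12 ependymal, 1 of 6 oligodendrocyte precursor, 2 of 4 endothelial and 2 of 4 mural genes.

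**Figure D2:**
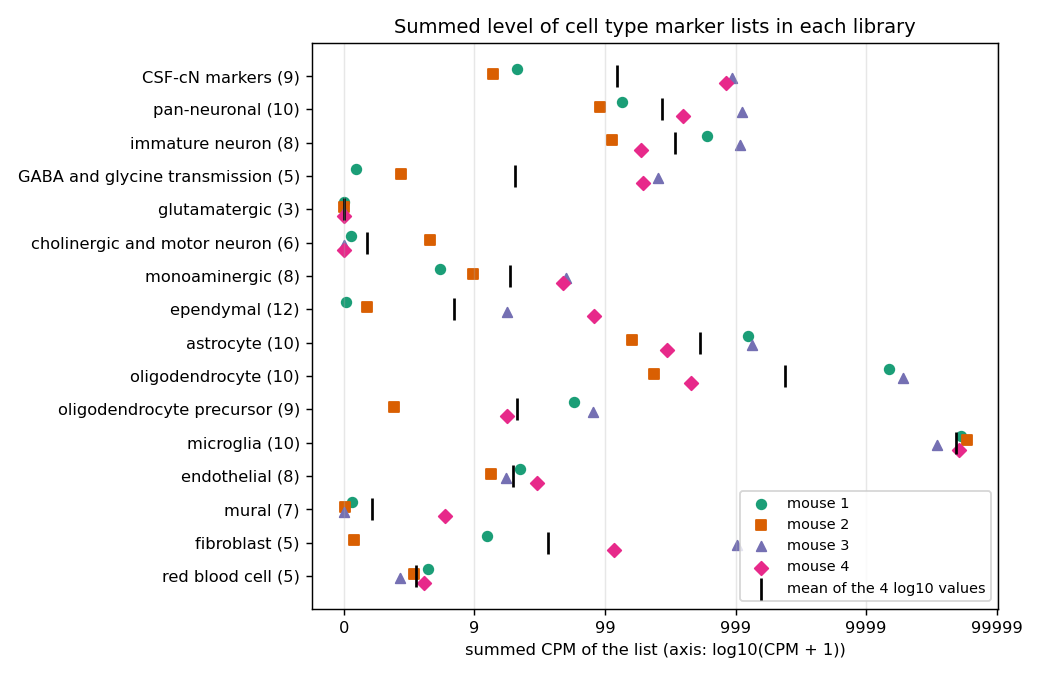
Summed level of each cell type marker list in each library. The horizontal axis is log10(CPM + 1) labelled in CPM, points are the 4 mice, the vertical bar is the mean of the 4 log values, and the number of genes in each list is in brackets; the microglia list lies between 35143 and 59245 CPM in all 4 libraries, and the oligodendrocyte list is higher in mice 1 and 3 than in mice 2 and 4.

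Neuronal genes were found in varying amounts. Of 10 pan-neuronal markers, 3 were called above 10 CPM (3 adjusted over the list alone), among them the synaptic gene Snap25 (19.9, 54.7, 385 and 167 CPM) and the ubiquitin hydrolase gene Uchl1 (78.6, 4.01, 272 and 66.7 CPM). The neuronal tubulin gene Tubb3 (12, 0.150, 144 and 38.9 CPM) and Stmn2 (0.241, 5.94, 115 and 28.4 CPM) were not called, but edgeR called Tubb3 without mouse 2 (adjusted p = 0.0048) and with no filter on counts (0.039) and Stmn2 without mouse 1 (adjusted p = 0.024). Without mice 1 and 2 the count of the list was 6. Of the immature neuron list, 2 of 5 tested members were called (2 adjusted over the list alone). These were Stmn1, a regulator of microtubules (552, 49.5, 1027 and 140 CPM), and the transcription factor gene Sox4 (50.2, 62.2, 17.7 and 31.1 CPM), while Dcx was at 0, 0, 13 and 10.5 CPM and Sox11 at 0.00926, 0, 17.4 and 5.77 CPM. Stmn1 had its higher values in mice 1 and 3, as Mbp did, and Sox4 in mice 1 and 2, so neither followed the CSF-cN markers.

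The opioid genes were examined because the series title names endogenous opioid signalling. Oprk1, the kappa opioid receptor gene, had 2, 5, 4700 and 5686 counts, or 0.0185, 0.0535, 54.5 and 63.4 CPM. The 95% Clopper-Pearson intervals were 0.00224 to 0.0669, 0.0174 to 0.12, 52.9 to 56.1 and 61.7 to 65.0 CPM. Oprm1, the mu receptor gene, stood at 0, 1.65, 0.209 and 4.17 CPM, the nociceptin receptor gene Oprl1 at 0.0185, 0, 20.0 and 0.156 CPM, and Oprd1, the delta receptor gene, had no count in any library. Of the genes for opioid peptide precursors, the dynorphin precursor gene Pdyn was at 0.0185, 6.04, 29.1 and 0.0111 CPM and the enkephalin precursor gene Penk at 0, 2.27, 13.8 and 2.12 CPM. Pomc was at 2.81, 3.45, 1.28 and 1.79 CPM and Pnoc at 0.130, 0, 2.02 and 9.67 CPM.

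Oprk1 lies on chromosome 1 from 5588466 to 5606131 on the plus strand of GRCm38 (gene ENSMUSG00000025905.13), and Pdyn on chromosome 2 from 129686565 to 129699844 on the minus strand (gene ENSMUSG00000027400.11). Over the 4 mice, Oprk1 had a mean of 29.5 ± 34.2 CPM (SD) and was not separated from 10 CPM (log2 1.56, SE 1.17, edgeR adjusted p = 0.32). edgeR called 0 of the 7 tested opioid genes above or below 10 CPM, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. DESeq2 called 0 but gave no adjusted p for 4 of the 7 (Oprl1, Pdyn, Penk and Pnoc), and limma-voom called 0 above and 2 below, Oprm1 and Oprl1. Without mice 1 and 2, edgeR called Oprk1 above 10 CPM (log2 2.62, adjusted p = 5.1e-04). This choice was made after the data were seen and keeps only mice 3 and 4, the libraries in which Oprk1 was high. The call therefore follows from the choice of samples and is not independent support.

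Within each mouse, the kappa receptor gene was set against the other opioid receptor genes as a log2 ratio of CPM + 1. The Oprk1 over Oprm1 ratio was 0.03, -1.33, 5.52 and 3.64, with a mean of 1.96 ± 3.17 (SD, n = 4; exact two-sided sign-flip permutation p = 0.375, Benjamini-Hochberg adjusted 0.48 over 9 pairs), and Oprk1 was the higher in mice 3 and 4 and the lower in mouse 2, while in mouse 1 its 2 counts are within what a count of 0 allows. The mean ratio was 1.82 ± 2.73 over Oprl1 (higher in mice 2, 3 and 4, with 5 counts against 0 in mouse 2; exact p = 0.25, adjusted 0.45). Oprd1 had no count, so its ratio could not turn negative and its test shows nothing. Pdyn over Penk was 0.13 ± 1.27 (higher in mice 2 and 3, lower in mouse 4 and, with 2 counts against 0, not separable in mouse 1; exact p = 0.875, adjusted 0.875), and its sign turned under several alternatives, for example -0.39 with values scaled by gene length. Pkd2l1 exceeded the ependymal gene Foxj1 in 4 of 4 mice (5.31 ± 3.90, exact p = 0.13, adjusted 0.28) and the polycystin gene Pkd2 in 2 of 4 (2.50 ± 5.05, exact p = 0.5, adjusted 0.56). Foxj1 had no count in mice 1 and 2, so its ratio could not turn negative there, and in mouse 2 Pkd2l1 had only 18 counts. In mice 3 and 4 the ratio over Foxj1 was 8.09 and 8.67. With 4 mice the sign-flip test cannot give an exact p below 0.13.

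Most genes of GABA synthesis and transport had their higher values in the libraries of mice 3 and 4. The GABA-synthesizing enzyme genes Gad1 and Gad2 were at 0.0185, 0.107, 110 and 124 CPM and at 0.00926, 0.0214, 76.5 and 42.2 CPM. The vesicular transporter gene Slc32a1 was lower, at 0.00926, 0.107, 5.16 and 1.70 CPM, and the glycine transporter gene Slc6a5 had counts in mouse 2 alone (1.52 CPM). No count was found for the vesicular glutamate transporter genes Slc17a6, Slc17a7 and Slc17a8 or for Chat, the acetylcholine-synthesizing enzyme gene. Slc18a3, which lies within the span of Chat, was at 3.61 CPM in mouse 2 and had no count in the other 3 mice. Of the monoaminergic list, the decarboxylase gene Ddc was at 0.0185, 0.449, 43.9 and 39.2 CPM and the vesicular transporter gene Slc18a2 at 4.46, 8.28, 5.39 and 7.47 CPM, while Th and Dbh had no count.

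edgeR called 0 of 5 tested GABA and glycine genes above 10 CPM, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05. Gad1 was called without mouse 1 (adjusted p = 0.047), and 3 members, among them Gad1 and Gad2, were called without mice 1 and 2. That choice, made after the data were seen, keeps only the libraries in which Gad1 and Gad2 were high. The count was also 0 of 2 tested cholinergic genes and 0 of 2 tested monoaminergic genes, at the unadjusted p as well, and no glutamatergic gene had enough counts for a test. limma-voom also called 0 members of these lists above 10 CPM, as did DESeq2, which gave no adjusted p for 2 of the 5 GABA and glycine genes and 1 of the 2 cholinergic genes. Below 10 CPM, limma-voom called 2 GABA and glycine genes, Slc32a1 and Slc6a5, and both cholinergic genes, and DESeq2 called 1 cholinergic gene. Slc32a1 was set against Slc6a5 within each mouse (mean log2 ratio 0.72 ± 1.66, SD, n = 4; exact sign-flip permutation p = 0.375, adjusted 0.48). It was the higher in mice 3 and 4 and the lower in mouse 2, and in mouse 1 its single count is within what a count of 0 allows. Its ratios to Slc17a6 and Chat could not turn negative, since these genes had no count, and their tests show nothing.

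Several genes of peptide storage also had their higher values in the libraries of mice 3 and 4. Of 12 dense-core vesicle genes, 4 were called above 10 CPM (4 adjusted over the list alone): the granin gene Scg2 (0.306, 3.05, 168 and 292 CPM), Pcsk1n (1.5, 1.15, 157 and 178 CPM), Scg5 (8.45, 0.182, 150 and 146 CPM) and the carboxypeptidase gene Cpe (315, 5.62, 587 and 362 CPM). The count was 1 without mouse 3 and 1 without mouse 4, with edgeR adjusted p between 0.052 and 0.152 for Scg2, Pcsk1n and Scg5. limma-voom also called 1. Neuropeptide precursors outside the opioid list were low, with 0 of 13 tested members called above 10 CPM by edgeR (0 adjusted over the list alone, 0 at the unadjusted p) and 0 by limma-voom and by DESeq2, which gave no adjusted p for 5 of the 13; limma-voom called 12 below 10 CPM and DESeq2 2. Their highest means were 3.11 ± 5.00 CPM for Apln and 2.21 ± 3.42 CPM for Cartpt (SD, n = 4).

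Of the 15 tested Gi/o signalling genes, through which opioid receptors act, 5 were called above 10 CPM (5 adjusted over the list alone). The G protein subunit gene Gnai2 had a mean of 519 ± 118 CPM (SD, n = 4), Gnai3 131 ± 46.3 CPM and the receptor kinase gene Grk2 77.0 ± 25.5 CPM, while Gnai1 varied between 5.53 CPM in mouse 2 and 200 CPM in mouse 3. Unlike most CSF-cN markers, Gnai2 (481, 668, 387 and 540 CPM) and Grk2 (58.4, 114, 62.9 and 72.3 CPM) were not confined to mice 3 and 4. Which cells carried this RNA was not tested. Of 22 tested PKD, TRP, ASIC, PIEZO and P2X channel genes, 4 were called (4 adjusted over the list alone), namely Trpm7 (113 ± 42.3 CPM), P2rx4 (108 ± 29.4 CPM), P2rx7 (89.9 ± 20.0 CPM) and Trpv2 (68.5 ± 16.2 CPM). These channel genes, too, were not confined to mice 3 and 4, and stood at 52.0 CPM or more in mice 1 and 2. Of 16 tested voltage-gated sodium and calcium channel genes, Cacna1d was called (22.5 ± 11.5 CPM, edgeR adjusted p = 0.045; 0 adjusted over the list alone), and the call was lost without mouse 2, 3 or 4 (adjusted p = 0.19, 0.14 and 0.20), with DESeq2 (0.13) and with limma-voom (0.10). The sodium channel genes Scn9a and Scn3a were at 25.3 and 20.2 CPM in mouse 3 and at 4.10 and 6.73 CPM in mouse 4.

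Among 26 tested ionotropic receptor genes, Glrb was called above 10 CPM (90.9, 1.19, 178 and 21.1 CPM; 0 adjusted over the list alone), and the call was lost without mouse 3 (edgeR adjusted p = 0.13) and with limma-voom (0.24). Grin2b was called below 10 CPM (0.00926, 0.0214, 0.0232 and 0.0669 CPM). The glutamate receptor gene Gria2 was at 0, 1.11, 12.7 and 47.4 CPM and the GABA receptor gene Gabra4 at 0, 0.0107, 7.97 and 44.2 CPM. Among 28 tested metabotropic receptor genes, 2 were called above 10 CPM (1 adjusted over the list alone) and Htr2b below it (0.0278, 0.0321, 0.128 and 0.0111 CPM). Adjusted over the list alone, neither Grin2b nor Htr2b was called; both were named after their values were seen. Among the genes called above was Calcrl (20.1 ± 2.99 CPM, SD, n = 4), whose call was lost without mouse 1 (adjusted p = 0.058), without mouse 4 (0.077), without mice 1 and 2 (0.12) and with DESeq2 (0.15).

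The series title also names proliferation, so growth factor and cell cycle genes were examined. Of 42 tested growth factor and morphogen genes, 5 were called above 10 CPM (5 adjusted over the list alone), among them Tgfb1 (79.3 ± 14.8 CPM, SD, n = 4), Tgfa (60.1 ± 14.1 CPM), Pdgfb (37.0 ± 9.26 CPM) and Pdgfa (32.0 ± 15.2 CPM). Unlike most CSF-cN markers, these named growth factor genes stood at 27.0 CPM or more in mice 1 and 2. Of 9 tested cell cycle genes the replication clamp gene Pcna was called (67.8 ± 2.93 CPM; 1 adjusted over the list alone). Mcm2 was at 7.38, 32.4, 5.59 and 7.72 CPM, Cdk1 at 0, 2.61, 1.61 and 8.69 CPM, and Top2a had counts in mouse 3 alone (5.15 CPM). All 12 dissociation and immediate early genes, which respond within minutes to tissue handling, were called (12 adjusted over the list alone), and they summed to 17238, 11204, 5679 and 9209 CPM. Fos had a mean of 2013 ± 782 CPM, Junb 1755 ± 629 CPM and Jun 1558 ± 642 CPM. Hspa1b stood at 1368 ± 1076 CPM, a value that is uncertain because it shares reads with its near-identical neighbour Hspa1a.

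The CSF-cN list was then set against each other cell type list within each mouse, as the difference of the median log2(CPM + 1) of the members. It lay below the microglia list by a mean log2 difference of -9.95 ± 2.57 (SD, n = 4), below the oligodendrocyte list (-4.29 ± 3.75) and below the pan-neuronal list (-1.94 ± 0.63), in 4 of 4 mice each (exact two-sided sign-flip permutation p = 0.13, the smallest that 4 mice allow, adjusted 0.31 over 15 lists). The CSF-cN median itself was 0.0525 and 0 in mice 1 and 2, so no difference could rise above these values there. The signs in mice 1 and 2, and the p-values that rest on them, are therefore not read as support. In mice 3 and 4 the differences were -7.12 and -8.45 for microglia, -5.20 and -0.185 for oligodendrocytes, and -1.55 and -1.36 for the pan-neuronal list. The mean difference was positive against the ependymal list (1.21 ± 1.79; 3.80 and 0.985 in mice 3 and 4, 0.0525 and -0.0154 in mice 1 and 2; exact p = 0.25, adjusted 0.31) and the astrocyte list (1.07 ± 2.27, positive in 2 of 4, exact p = 0.5, adjusted 0.5). Against the GABA and glycine list it was -0.72 ± 0.79 (negative in 3 of 4, exact p = 0.25, adjusted 0.31), and it turned to 0.46 with the mean of members in place of the median. The differences from the remaining 9 lists ranged from 0.85 for fibroblasts to 2.03 for the glutamatergic list, whose members had no count. The glutamatergic, cholinergic and monoaminergic lists had a median of 0 in all 4 mice. Their differences could not turn negative, so their tests are not read, though they stay in the adjustment. For the others of these lists the adjusted sign-flip p ranged from 0.31 to 0.5. Among them, the medians of the mural and endothelial lists were at most 0.0160 and 0.0315.

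Variation between the mice was then measured. Of the 18522 tested genes, 6759 were at 10 CPM or more in all 4 libraries, 7665 in none and the others in some. Spearman correlations across all tested genes lay between 0.801 and 0.861 for the 6 pairs of libraries, where genes are not independent replicates, and the common biological coefficient of variation was 1.45. Among the 1815 genes with a mean of at least 100 CPM, the median SD of log2(CPM + 1) over mice was 0.36. The SD was under 0.5 in 1334 of them and over 2 in 78. The 10 genes with the largest SD included the tdTomato transgene, Zcchc12 (0.0926, 0.118, 402 and 441 CPM) and Dcn. The others were Ugt8a, Klk6, Ermn, Apod, Enpp6, Gsn and Enpp2, which stood at 276 to 3123 CPM in mice 1 and 3 and at 0.123 to 10.8 CPM in mice 2 and 4.

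**Figure D3:**
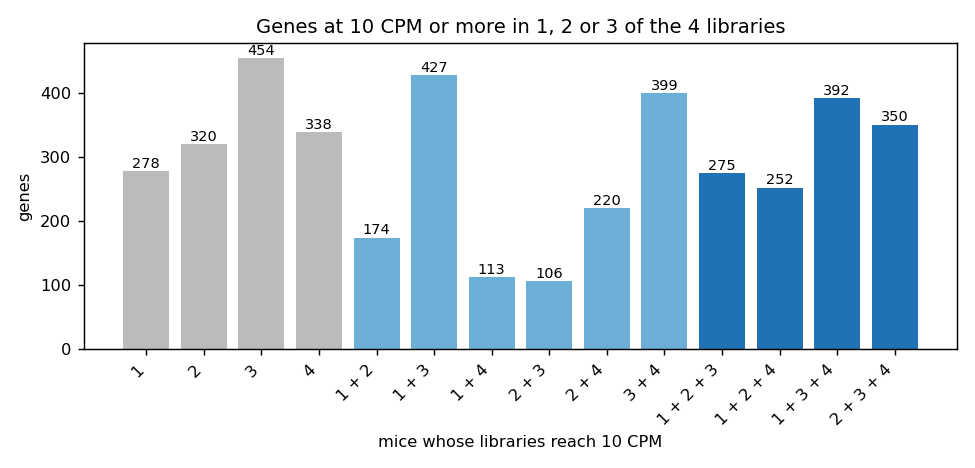
Number of tested genes at 10 CPM or more in the libraries of the mice named on the horizontal axis and below 10 CPM in the others. Bars start at 0; of the pairs of libraries, mice 1 and 3 shared 427 such genes and mice 3 and 4 shared 399, while mice 2 and 3 shared 106.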

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

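All tests of explanations in this part were chosen after the results were seen. Within each set of 4 libraries, a log2(CPM + 1) value was singled out when its gap to the nearest other library, divided by the range of the 4, exceeded Dixon's 95% critical value. This happened in 18 of 151 sets tested. Chance would give about 7.55 for independent, normally distributed values, which these are not: a gene with counts in a single library has a ratio of 1 whatever its level, and list sums share members with the named genes. The number of sets therefore does not show whether there is an excess.

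Single libraries stood apart as follows. In mouse 3 these were Oprl1 (20.0 CPM, ratio 0.952) and Top2a (5.15 CPM, ratio 1). In mouse 4 they were the ependymal genes Ccdc153 (15.8 CPM, 0.993) and Rarres2 (10.2 CPM, 0.996), the contractile genes Acta2 (2.61 CPM, 0.975) and Tagln (2.21 CPM, 1), and Vtn (0.167 CPM, 1) and Lum (0.769 CPM, 1). In mouse 2 they were Slc6a5 (1.52 CPM, 1) and Slc18a3 (3.61 CPM, 1). In mouse 1 they were Prph (0.130 CPM, 1), Rgs5 (0.157 CPM, 0.924) and Adrb1 (31.5 CPM against 13.4 to 13.6 in the other mice, 0.979). Of the remaining genes, Tal1 was low in mouse 1 (0.898 CPM, 0.841), Cpe was low in mouse 2 (5.62 CPM, 0.862) and Pcna was high in mouse 3 (72.2 CPM against 66.0 to 66.8, 0.877). The summed cholinergic and motor neuron list was high in mouse 2 (3.61 CPM, 0.920) and the mural list in mouse 4 (4.99 CPM, 0.924).

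The count table holds a further construct row, PC.G5.tdT, that no comparison used. It had 0, 8, 760 and 9924 counts in mice 1, 2, 3 and 4, above the 3 counts that a count of 0 allows in mice 2, 3 and 4. In mice 2, 3 and 4 this was 13.8%, 5.62% and 6.47% of the counts of the injected transgene's row. What this construct is is not given in the sources used here. Whether its row takes reads of the injected transgene, or the reverse, was not determined, so the counts of both rows are uncertain. Another construct row, CRE.ERT2, had 1 count, in mouse 4.

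Most CSF-cN markers were near 0 CPM in the libraries of mice 1 and 2; Pkd2l1 stood at 17.9 and 0.193 CPM there, Tal1 at 0.898 and 10.3 CPM and Espn at 1.44 and 2.39 CPM. Lower depth is excluded, since the lower total of these libraries was 1.112 times the higher total of the other libraries. The scaling is excluded too, because the raw summed counts of the list gave a ratio of 0.02887 between the higher of these libraries and the lower of the others. Few transgene-expressing cells in the sorts of mice 1 and 2 may account for the low markers, as the transgene CPM gave a ratio of 0.003957 in the same comparison. The low transgene counts of these mice were already known, so this ratio is not independent support. Pkd2l1 also did not follow the transgene in proportion. It stood at 17.9 CPM with 5 transgene counts in mouse 1. In mice 3 and 4 it stood at 664 and 690 CPM with the transgene at 157 and 1709 CPM. A low virus dose, a shifted sort gate and a sample from an uninjected animal remain open, and the design names no biological difference between the mice that could be tested.

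Microglial genes were among the most abundant in every library, although the sort was for tdTomato. In mice 1 and 2, almost without transgene counts, microglia rich in transgene RNA do not account for it. The lower microglia list sum of these mice was 1.042 times the higher sum of mice 3 and 4. This comparison cannot exclude such microglia in mice 3 and 4, and transgene RNA does not measure the tdTomato protein used for the sort. Free RNA of the whole dissociated cord is also argued against, since the oligodendrocyte list reached at most 0.8969% of the microglia list in mice 2 and 4. How this RNA, with P2ry12 at 7288 ± 1381 CPM (SD, n = 4) and C1qb at 6624 ± 1867 CPM, came into the sorted samples remains open: microglial cells that passed the gates were not tested for apart from the genes that raised the question, and no biological explanation was tested.

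Oligodendrocyte genes were high in mice 1 and 3. A deeper library of mouse 3 is excluded, as its total was 0.9694 times the lower total of mice 2 and 4. This ratio does not cover mouse 1, whose total was the highest (115479640 against 95186395 and 85626022 in mice 2 and 4). The list sums, already scaled to library size, differed far more than these totals: 15065 CPM in mouse 1 against 238 and 459 CPM in mice 2 and 4. Mbp was at 1312, 31.3, 1690 and 217 CPM and Cnp at 898, 103, 1440 and 70.5 CPM. The source of this RNA remains open, since whole cells, fragments and free RNA were not tested apart from the genes that show the pattern. Differences in dissociation or gating between the mice remain open, and no biological explanation was tested.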

How the results depend on the processing

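No paired analysis was possible because the series has a single group. Leaving out mice 1 and 2 was the only alternative added after the data were seen. The count of genes above 10 CPM stayed between 6147 and 6893 under the other scalings, filters, tests and left-out mice, and 6075 of the 6352 genes called without mice 1 and 2 were shared with the 6795. It was 10954 against 1 CPM and 1078 against 100 CPM, which asks a different question. The count of genes below 10 CPM, 123, was not stable: it was 0 without any single mouse and without mice 1 and 2, 2041 with DESeq2, 6164 with limma-voom, 2485 with no filter, 256 with 10 counts in 2 samples, 6 against 1 CPM and 9029 against 100 CPM. Fewer mice leave the test less power, and limma-voom's mean of logs lies below the mean; other causes were not tested. The 1 CSF-cN marker above 10 CPM became 0 with limma-voom and against 100 CPM, 5 against 1 CPM and 3 without mice 1 and 2. The 0 opioid genes became 2 against 1 CPM and 1 without mice 1 and 2.

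The CSF-cN minus GABA and glycine difference turned to 0.46 with the mean of members. Pdyn over Penk turned to -0.30 without mice 1 and 2, -0.41 with a pseudocount of 0.1, -0.39 scaled by gene length and -0.67 in the authors' log2 table, and ranged from -0.19 to 0.72 over the left-out mice. The causes were not tested.

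The following named genes changed the sign of their log2 level relative to 10 CPM, in each case without passing the threshold after the change. With limma-voom they were Oprk1 (-3.05), Pkd1l2 (-3.41), Myo3b (-3.50), Tubb3 (-0.0681), Stmn2 (-0.58), Gad1 (-2.45), Gad2 (-3.51), Ddc (-2.62), Olig1 (-2.0), Sox10 (-3.51), Dcn (-0.11), Gria2 (-3.21), Gabra4 (-4.81), Adora1 (-2.26), the transgene AAV2.CAG.tdT (-0.51), Zcchc12 (-1.02) and Enpp6 (-0.47). Without mice 1 and 2 they were Oprl1 (0.0734), Pdyn (0.60), Gata2 (0.64), Gata3 (0.30), Tal1 (0.42), Tal2 (0.43), Espn (0.60), Dcx (0.30), Sox11 (0.27), Fam183b (0.0602), Tnr (0.24), Igf2 (0.91), Scn9a (0.62), Scn3a (0.49), Gabrb1 (0.90) and Mcm2 (-0.53). With total counts only it was Igf2 (0.0184). Over the left-out mice the level ranged from -2.34 to 0.26 for Pdyn, -2.42 to 0.0234 for Gata2, -0.48 to 0.29 for Tal1, -0.96 to 0.10 for Espn, -1.35 to 0.20 for Gfap, -0.16 to 0.92 for Olig1, -0.30 to 0.75 for Sox10, -1.63 to 0.39 for Igf2, -2.88 to 0.00153 for Scn9a, -1.15 to 1.06 for Gria2, -1.94 to 0.83 for Gabra4, -1.12 to 0.32 for Gabrb1, -0.33 to 0.60 for Adora1 and -0.53 to 0.64 for Mcm2. Of the named genes called in the main analysis, edgeR without mouse 1, 2, 3 and 4 lost 2, 1, 7 and 7 and gained 2, 1, 0 and 0. DESeq2 lost 2 and gained 3, not counting genes such as Dcn and the transgene, for which it gave no adjusted p. limma-voom lost 11 and gained 22, and leaving out mice 1 and 2 lost 1 and gained 9. These numbers leave out the genes that changed sign, of which Dcn, the transgene, Zcchc12 and Enpp6 also lost their calls with limma-voom. The calls gained with DESeq2 and limma-voom were all below 10 CPM, and those gained without mice 1 and 2 all above it. With no filter edgeR gained 1, Tubb3. The causes of these changes were not tested.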

Other observations

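All lists of this part were chosen after the data were seen. Genes induced by interferon had different levels in the 4 mice: a list of 12 summed to 233, 655, 152 and 752 CPM in mice 1, 2, 3 and 4. Irf7, a transcription factor of this response, was at 7.76, 77.5, 2.05 and 45.9 CPM, the antiviral gene Rsad2 at 0.0185, 43.1, 1.32 and 34.5 CPM, and Ifit3 at 20.0, 85.3, 12.7 and 179 CPM, whereas Ifit1 was at 25.3, 4.64, 0.383 and 40.1 CPM. A list of 7 genes of activated microglia summed to 2481, 6626, 1661 and 2780 CPM, most of it Apoe (2123, 6023, 1489 and 2318 CPM), and Clec7a was at 288, 209, 73.0 and 287 CPM, while Spp1 was at 5.76, 99.3, 1.82 and 5.36 CPM and Cst7 at 9.06, 96.4, 22.5 and 28.3 CPM. Macrophages of the brain borders gave little signal, with 83.7, 34.8, 51.3 and 70.5 CPM over 6 genes. The 7 genes of other leukocytes had no counts except Cd4 in mouse 3 (4.15 CPM), and 4 Schwann cell genes summed to 3.00, 0, 3.18 and 0.0223 CPM.

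Pkd2l1 and the transgene were not in a fixed ratio. Pkd2l1 had 386, 0.310, 4.23 and 0.404 counts per count of the injected transgene in mice 1, 2, 3 and 4. In mouse 1 Pkd2l1 stood at 17.9 CPM with 5 transgene counts, and Gad1 had 2 counts there.

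Oprk1 was 1 of 399 tested genes at 10 CPM or more in the libraries of mice 3 and 4 and below it in the others. With 4 pooled libraries, the co-expression of Oprk1 and Pkd2l1 in the same cell was not measured, and which cells carried Oprk1 remains open. Pdyn did not share the pattern: it was at 29.1 CPM in mouse 3 and at 0.0111 CPM in mouse 4.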
